A study of Mus musculus with 2 samples.

How the data were processed

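Per the labels' protocols, C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes in low serum, were differentiated and lysed, and RNA bound to YTHDF2 was recovered with an antibody (RNA immunoprecipitation, RIP). The series compared 1 YTHDF2 RIP library with 1 input library of the same cells, both with batch label 1. An IgG control is named in the design text and was not analysed here. The protocol describes paired-end sequencing, and its library steps after the pulldown are worded for DNA. Reads were aligned to mm10 with Bowtie and peaks were called with MACS, per the series' design text. FastQC, Trim Galore, Picard, HOMER, deepTools and DiffBind are also listed, per the submitters' processing notes, and their versions and settings are not given in the sources used here.

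The authors deposited 1 list of 9271 peaks called on the RIP library over input, so no value has a replicate. Its columns hold, per the file headers, the pileup signal at the summit, the fold enrichment (a linear ratio over the local input background), and −log10 of the p-value and of the q-value. A table the authors deposited pairs 1541 of the peaks with genes and marks the start codon, stop codon, coding sequence and untranslated regions each peak touches, and another gives the number and percent of peaks per element. The authors' deposited table of KEGG pathways and that of Gene Ontology (GO) terms give the number of annotated and of peak genes, a p-value named as Fisher's test and its FDR. Scores per peak are the authors' own and were used only to describe, rank or filter peaks within that list. A file that repeats the gene table with empty function columns and one that repeats the marked KEGG pathways were not used.

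The depth of either library is unknown, since no file gives a total count. All pileup values were whole multiples of 0.9 (tolerance 1e-06), and 1 step was read as 1 RIP fragment scaled by the caller. The input background at each summit was computed from pileup and fold enrichment, each with 1 added to numerator and denominator. A Poisson tail with that background gave the deposited −log10 p-value within 0.01 for 100% of peaks. The background was a whole number (tolerance 0.01) for 59.9% of peaks and stood at the lowest value, 1.08, for 466 peaks. The other 3250 backgrounds were multiples of the shortest peak, 186 bp, per 10000 bp. Intervals on fold enrichment are exact 95% Poisson intervals of the RIP fragments at the summit. They cover counting error of the RIP library only, hold the background fixed, and take fragments as independent, which PCR copies are not.

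Positions are 1-based coordinates of mm10 as the authors gave them. The reference used for annotation and sequence was GRCm38, the same build, with GENCODE M21 gene models. Peaks outside the authors' gene table were placed by overlap of at least 1 bp with exons, then with gene bodies. Of the authors' 1285 genes, 1284 were matched to GENCODE M21, 1269 by symbol, 12 through synonyms and 3 by position, among them 2 symbols that a spreadsheet had turned into dates. The authors' rule for a peak that touches several elements is not stated. A rebuilt rule (stop codon, start codon, coding sequence, 3' UTR, then 5' UTR) gave 690 peaks in 3' UTRs against their 688, and was used where peaks were filtered.

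Gene lists were fixed before the data were examined: 24 by name and 5 by symbol pattern. For the 26 lists with at least 5 protein-coding members, the number of members in the authors' gene table was set against 10000 random lists of the same size, drawn from 21728 protein-coding genes and matched on 10 strata of gene length. A list was called above or below if its percentile passed 97.5 or 2.5. Long non-coding RNAs, mitochondrially encoded transcripts and small nucleolar RNAs with their hosts had too few protein-coding members and were given as counts. For lists with at least 5 members in the table, the median of each gene's highest fold enrichment was set against random lists matched on peaks per gene. Percentiles describe these libraries and are no test of a condition. Expression is not known here, so occupancy also follows expression.

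DRACH (D is A, G or U, R is A or G, H is A, C or U) is the consensus around N6-methyladenosine (m6A), the mark YTHDF2 reads. Its density on the strand of the gene was compared with windows shifted by 1 peak width to either side, with a bootstrap 95% interval over peaks (1000 draws), and with 5 dinucleotide shuffles of each peak. The shift was along the genome, so windows beside exon peaks can lie in introns or outside the gene. Windows themselves were not shuffled. Shares of peaks carry Wilson 95% intervals. Both kinds of interval cover counting of peaks only and take peaks as independent, although many can lie in 1 gene.

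Named genes followed a rule fixed before the data were examined: the 15 genes of highest fold enrichment, the 10 with most peaks, the 10 of smallest q-value, up to 4 members per list by fold enrichment, every m6A list member with a peak, the 8 KEGG pathways of lowest p-value and 5 GO terms per ontology. Clone names were left out. The text gives part of the genes so named. The peak-table result of 1 gene list is not reported here. Alternatives were stricter peak thresholds, other gene assignments, other matching, other control sequence and other marks of significance.

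Analyses ran in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. The functions were tested on simulated data. Of 200 simulated lists with no effect among 20000 genes, 1.5% fell outside the range, and 93.0% of lists given 4 times the peaks were called above. Genes were given peaks more often in that simulation than in these data, so the share called above may be lower here. Of simulated lists of long genes with no effect, 4.0% fell outside with length matching and 17.5% without it, so calls without matching are less reliable. Of 100 simulated lists with no effect on median fold enrichment, 7.0% fell outside. For motif ratios over 1500 simulated peaks in 400 runs, 93.8% of the 95% intervals held a true value of 1.0 and 95.2% held a true value of 1.2.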

Results

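The data were sequenced fragments from an RNA immunoprecipitation in C2C12 myotubes. The antibody was to YTHDF2, a cytoplasmic reader of m6A that recruits the deadenylation machinery. Whether DNA was removed before the library steps is not given. There was 1 YTHDF2 RIP library and 1 input library, with no replicate, so no difference could be set against replicate spread. The comparison of RIP with input asks which RNAs, and which parts of them, YTHDF2 bound. The median peak held 29 RIP fragments at its summit (quartiles 20 and 46, range 8 to 349).

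The RIP library gave 9271 peaks over input, on the 19 autosomes and X, and the authors' table placed 1541 of them in 1285 genes. The strongest gene was Anapc10, a subunit of the anaphase-promoting ubiquitin ligase, with a fold enrichment of 13.8 (95% counting interval 10.0 to 18.6). It was followed by the proteasome assembly chaperone Psmg2 at 12.6 (8.52 to 18.0), the mitochondrial tRNA methyltransferase Trmt10c at 11.9 (9.23 to 15.1) and the mitochondrial methionyl-tRNA formyltransferase Mtfmt at 11.4 (8.15 to 15.6). Cox7b, a cytochrome c oxidase subunit, and Coa6, an assembly factor of that complex, reached 10.8 (8.28 to 13.9) and 10.5 (7.40 to 14.6). These intervals overlap, so the order among the leading genes was not resolved at this depth.

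The Anapc10 peak lay on chromosome 8 from 79775025 to 79775276 and spanned the stop codon. The Psmg2 peak, in coding sequence, lay on chromosome 18 from 67648775 to 67648978. The Trmt10c peak, also over the stop codon, lay on chromosome 16 from 56033832 to 56034097, and the Mtfmt peak, over the start codon, on chromosome 9 from 65435815 to 65436034. Peaks in 3' UTRs included Brcc3 at 11.3 (7.47 to 16.4), Casc4 at 11.0 (8.44 to 14.2), Tmed5 at 10.4 (8.22 to 13.0) and the secreted guidance factor Sema3c at 10.2 (6.84 to 14.6). Several of these folds rested on few fragments over a low background: 28 RIP fragments for Psmg2 and 25 for Brcc3, both at the lowest background of 1.08.

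Genes of smallest q-value held more fragments. The proteasome ATPase Psmc6 had 122 fragments and a fold enrichment of 8.52 (7.09 to 10.2) over its stop codon, on chromosome 14 from 45348574 to 45348885. The splicing regulator Tra2a had 97 fragments and 9.81 (7.98 to 11.9), and the corepressor Ncor1 had 101 fragments and 7.07 (5.77 to 8.57) in its 3' UTR. Dcun1d5, with 164 fragments, stood at 4.95 (4.23 to 5.77) over its start codon. In the authors' gene table most genes, 1067, had 1 peak and 218 had more. Rbm26, Syncrip, Rock2 and Phip had 6 peaks each, the highest number in that table, and Cenpf and Luc7l2 had 5. The gene count is 392 with peaks at or above the median fold enrichment of 4.40, and 3284 protein-coding genes if every peak in a gene body is taken.

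By the authors' element table, 3' UTRs held 688 of the 1541 peaks with genes, 44.6% (Wilson 95% interval 42.2 to 47.1). Coding sequence held 351, 22.8% (20.8 to 24.9), stop codons 246, 16.0% (14.2 to 17.9), 5' UTRs 145, 9.41% (8.05 to 11.0), and start codons 111, 7.20% (6.02 to 8.60). By peak centre in GENCODE M21, 62.9% (60.3 to 65.5) of 1329 centres in coding transcripts lay in 3' UTRs, which make up 54.7% of those elements' bases in the authors' genes, a ratio of 1.15 (1.10 to 1.20). The ratio for 5' UTRs was as high, at 1.18 (1.01 to 1.39). Coding sequence was below its share of bases, at a ratio of 0.737 (0.675 to 0.804).

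**Figure D1:**
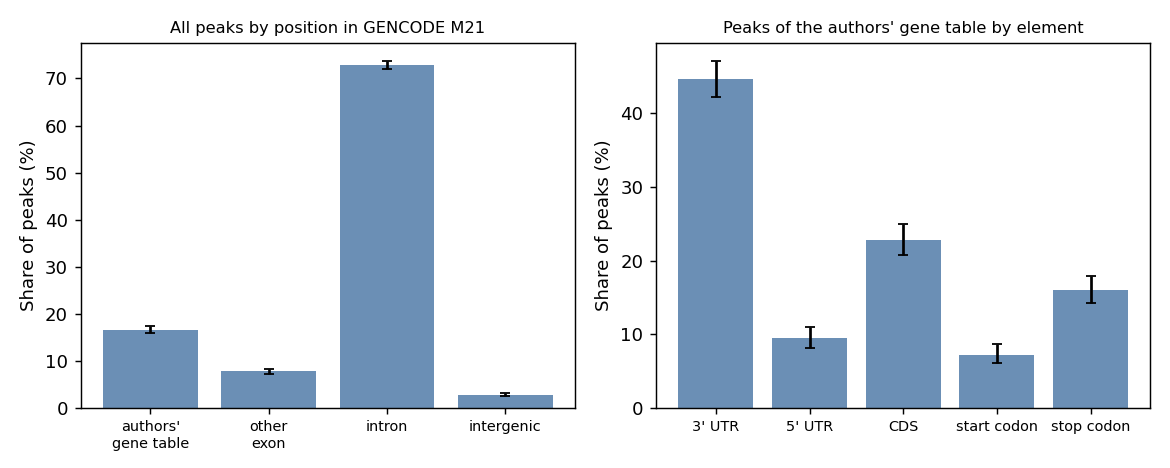
Share of peaks (%), with Wilson 95% intervals, by position of all 9271 peaks (left) and by the authors' element for 1541 peaks with genes (right). Introns held 72.9% of all peaks, and 3' UTRs 44.6% of the peaks with genes.

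Most peaks were outside the authors' gene table. Introns held 6757 peaks, 72.9% (72.0 to 73.8), other exons 718, and the space between genes 255. By centre, 97.1% (96.7 to 97.4) of peaks lay in gene bodies, which cover 47.4% of the genome, and 21.1% (20.3 to 21.9) lay in exons, which cover 4.95%. Intron peaks had a median fold enrichment of 4.63 (quartiles 3.63 and 5.77) over a median background of 4.09, and peaks listed with genes by the authors had 3.25 (2.42 and 4.53) over 15.0. At like background, a split chosen after seeing the data, exon and intron peaks had close medians: 6.10 and 6.10 under a background of 2, 4.50 and 4.34 from 4 to 8, and 2.11 and 2.16 at 32 or more. The caller's threshold sets the lowest fold a peak can have at a given background, so close medians are partly fixed.

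**Figure D2:**
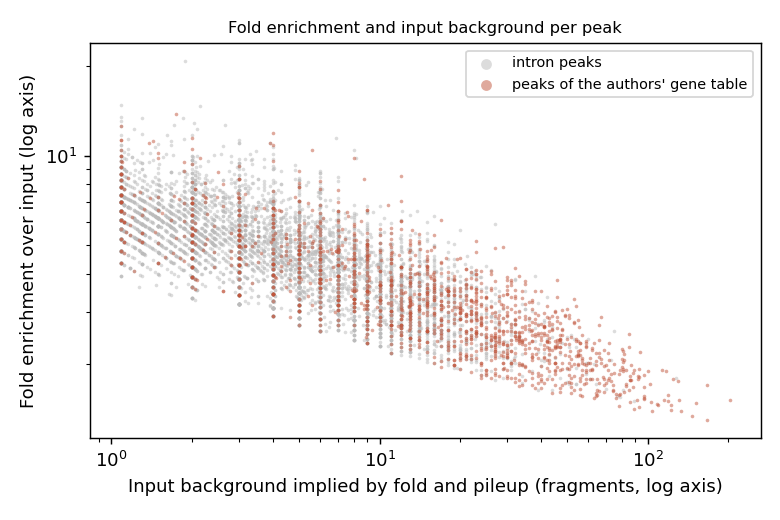
Fold enrichment against the input background implied at the summit, both on log axes, 1 point per peak. Peaks of the authors' gene table reach higher backgrounds (median 15.0) than intron peaks (median 4.09), and fold enrichment falls as background rises in both. Part of that fall is fixed in advance, since background divides the fold and only peaks past the caller's threshold are listed.

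Among the 26 gene lists compared with random lists, 3 had more members with a peak and 1 had fewer, with no allowance for the number of lists. Random lists were drawn from all protein-coding genes, expressed or not. TGF-beta and BMP signalling had 7 of 24 members where random lists averaged 2.01 (percentile 99.8). These included the ligand Tgfb2 at 4.80 (2.55 to 8.43), the signal transducer Smad2 at 3.71 (2.90 to 4.68), the receptor Bmpr2 at 3.45 (2.79 to 4.23) and the activin subunit Inhba at 3.22 (2.40 to 4.24). Cytosolic ribosomal proteins had 7 of 82 (mean 2.31, percentile 99.6), with low folds such as Rps9 at 3.01 (2.24 to 3.95) and Rpl23 at 2.95 (2.31 to 3.71). The m6A writers, erasers and readers had 5 of 24 (mean 1.72, percentile 98.5): Ythdc2 at 8.69 (5.43 to 13.3), Rbmx at 4.82 (3.33 to 6.77), the writer component Zc3h13 at 3.84 (3.21 to 4.55), Hnrnpc at 2.53 (1.70 to 3.64) and Ythdf3 at 2.12 (1.67 to 2.66). Olfactory and vomeronasal receptors, not expected in muscle, had 2 of 1464 (mean 54.8, percentile 0): Olfr810 and Olfr805. The 3 lists above the range were within it when peaks had to reach a fold enrichment of 4 or a q-value of 1e-05. The m6A list was also within it with random lists matched on exonic length (mean 2.11, percentile 96.2), and the ribosomal list without length matching (mean 4.80, percentile 84.8).

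By the authors' gene table, muscle lists lay within the range of random lists. Myogenic regulators and fusion genes had 3 of 24 members (percentile 90.7), among them the transcription factor Mef2a at 6.58 (4.88 to 8.70) and the splicing regulator Mbnl1 at 1.93 (1.67 to 2.21). Sarcomere genes had 4 of 38 (percentile 85.4): the myosin light chain Mylpf at 4.22 (2.84 to 6.06), nebulin (Neb) at 3.44 (2.12 to 5.32), Tnnt1 at 3.04 (2.15 to 4.17) and Tnni2 at 1.76 (1.40 to 2.19). Excitation-contraction coupling had 1 of 24, Trdn, and the dystrophin complex 2 of 20, Utrn and Itgb1. Over gene bodies, an assignment chosen after seeing the data, the dystrophin list was above the range (percentile 98.4). Atrophy genes and muscle ubiquitin ligases had 0 of 23 and glycolysis 0 of 19, which random lists also reached (percentiles 10.4 and 16.3). Their ranges began at 0, so a shortage could not have been called there.

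Insulin, IGF, AKT and mTOR signalling had 5 of 24 members, at percentile 97.4 just within the range, with Rictor at 5.41 (4.20 to 6.87), Rps6kb1 at 5.07 (3.48 to 7.16) and Igf1 at 4.18 (3.41 to 5.07). It was above the range at a fold enrichment of 4 or more, with 3 members (mean 0.717, percentile 97.9), and without length matching (percentile 99.3), but within it at or above the median fold enrichment (percentile 93.1), at a q-value of 1e-05 (percentile 87.9) and with matching on exonic length (percentile 91.3). Deadenylation and decay factors had 4 of 28 (percentile 92.7), with Rida, the adaptor between YTHDF2 and RNase P/MRP, at 9.25 (6.68 to 12.5), Cnot4 at 4.52 (3.08 to 6.41) and Cnot1 at 3.27 (2.62 to 4.02). Published YTHDF2 substrates had 3 of 18 (percentile 91.6): Egfr at 5.55 (3.22 to 9.03), Atg5 at 1.83 (1.40 to 2.36) and Runx1 at 1.41 (1.21 to 1.62). Only 1 of 18 had a peak at a q-value of 1e-05 (percentile 57.0). Autophagy and lysosome genes had 4 of 24 (percentile 95.8), extracellular matrix and adhesion 4 of 24 (percentile 91.3), and replication-dependent histones 3 of 68 (percentile 91.8). Cell cycle genes had 3 of 28 (percentile 85.0), Wnt and Notch 3 of 24 (percentile 85.2), nuclear oxidative phosphorylation 2 of 25 (percentile 80.1), and chromatin regulators 3 of 28 (percentile 65.5, but 99.4 when 2 or more peaks per gene were required).

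Markers of neurons, hepatocytes, immune cells, and endothelial cells and adipocytes had 0 members with a peak each, of 24, 20, 20 and 18. That is within the range of random lists (percentiles 5.70, 16.5, 20.2 and 14.4). The range began at 0 for each list, so a shortage could not have been called. Myoblast and reserve cell markers had 2 of 16, Hgf and Bcl2 (percentile 78.9). Peaks touching an exon of any gene lay over 3 of 16 long non-coding RNA genes. They lay over 3 of 154 small nucleolar RNAs and their hosts, and 0 peaks lay on the mitochondrial genome. Of the 4 lists with at least 5 members in the table, 0 had a median fold enrichment outside the range of random lists: 3.84 for the m6A list, 4.18 for insulin and mTOR, 3.22 for TGF-beta and BMP and 2.59 for ribosomal proteins.

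**Figure D3:**
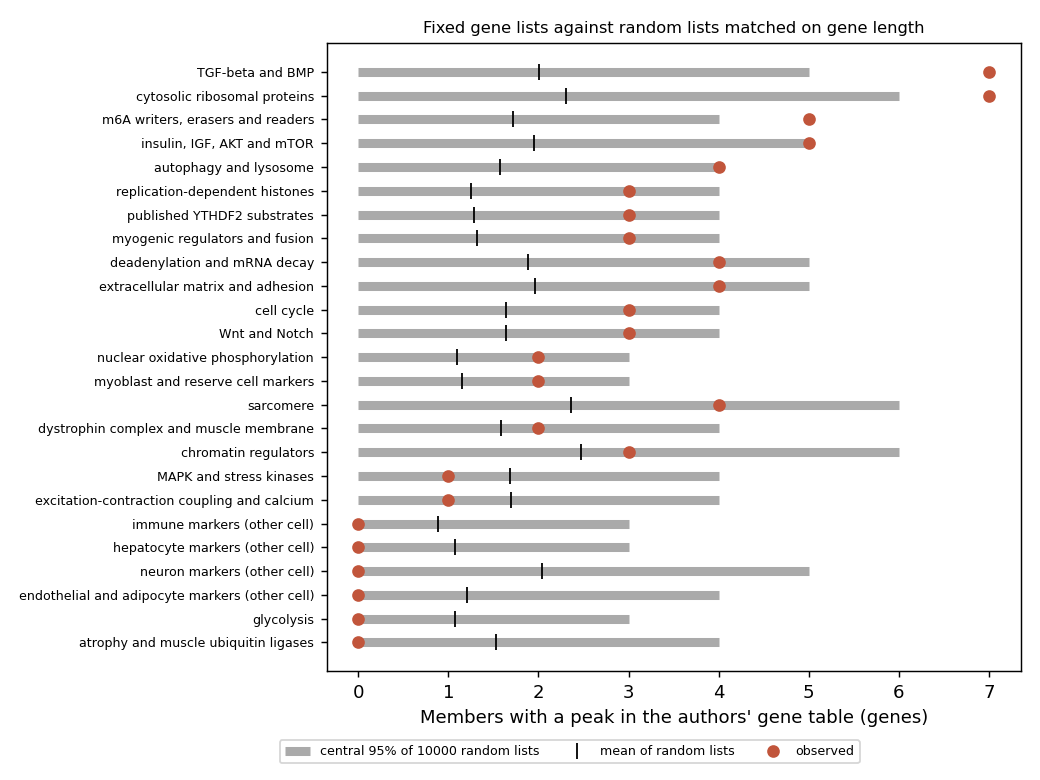
Members with a peak in the authors' gene table (genes, horizontal axis) for 25 lists, as points, against the mean (tick) and the central 95% (grey bar) of 10000 random lists matched on gene length. TGF-beta and BMP (7), ribosomal proteins (7) and the m6A list (5) lie right of their bars; the olfactory and vomeronasal list is not drawn.

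The KEGG pathway of lowest p-value was ubiquitin mediated proteolysis, with 20 of 129 genes where 7.50 were expected (p = 4.75e-05, FDR 0.0104, Fisher's exact test in the authors' deposited table). These genes included Anapc10, Mdm2, Itch and Ube3a. Regulation of actin cytoskeleton followed with 26 of 205 genes (FDR 0.0138, authors' deposited table), including Rock2, Mylpf and Itgav, then pathways in cancer with 33 of 313 and focal adhesion with 23 of 191 (FDR 0.0358 for each, authors' deposited table). RNA transport (18 of 142), pancreatic cancer (11 of 69), TGF-beta signaling (12 of 80) and ribosome biogenesis (11 of 70) had an FDR of 0.0531 in the authors' deposited table. The authors marked 40 of 219 pathways by unadjusted p-value, and 4 had an FDR under 0.05.

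The GO terms of lowest p-value were broad. Cellular macromolecule metabolic process held 462 genes where 322 were expected, and nucleic acid metabolic process 309 where 201 were expected, in the authors' deposited table. Intracellular organelle held 679 where 504 were expected. RNA binding held 74 where 37.7 were expected (FDR 4.9e-06, Fisher's exact test in the authors' deposited table), and ubiquitin-like protein transferase activity 34 where 13.4 were expected (FDR 8.4e-05, same test and table). The authors marked 1098 of 7030 terms, and 381 had an FDR under 0.05. The backgrounds were annotated genes, 6499 for KEGG and 13184 for biological process, not genes expressed in myotubes.

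The DRACH consensus was less dense in peaks than beside them, at 17.9 per kb against 19.5, a ratio of 0.919 (95% bootstrap interval 0.909 to 0.930). By element, a split chosen after seeing the data, peaks over the stop codon were an exception in direction, with a ratio of 1.04 (0.980 to 1.10) that includes 1. Peaks in 3' UTRs stood at 0.935 (0.898 to 0.974), in coding sequence at 0.926 (0.868 to 0.986), in 5' UTRs at 0.896 (0.802 to 0.998) and over start codons at 0.778 (0.679 to 0.888). GGACH, a narrower form of the consensus, was denser in peaks, with a ratio of 1.11 (1.08 to 1.15). In the same split it stood at 1.37 (1.14 to 1.62) over stop codons, 1.22 (1.03 to 1.44) in coding sequence, 1.16 (1.01 to 1.32) in 3' UTRs, 1.05 (0.848 to 1.27) in 5' UTRs and 0.890 (0.684 to 1.15) over start codons. Windows beside exon peaks can lie in introns or outside the gene. Ratios by element, for DRACH and GGACH alike, therefore mix that difference in sequence with any effect of the peaks. Peaks were richer in G than windows 5 widths away (24.4% against 20.5%), and against dinucleotide-shuffled peak sequence GGACH stood at 0.915 (0.891 to 0.939), a control chosen after seeing the data. Windows were not compared with their own shuffles, so that value does not set peaks apart from neighbouring sequence.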

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

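Genes by protein-coding bodies, lists over gene bodies and the intron share were chosen after seeing the data, as were DRACH in intron peaks, unmasked peaks and the authors' peaks, and GGACH against shuffled sequence. The DRACH ratio stayed below 1, with its interval, in all 11 alternatives except GGACH against adjacent windows, where it was 1.11. There were 5529 peaks at a fold enrichment of 4 or more and 4643 at or above the median. Genes numbered 478 and 392 under those filters, 218 with 2 or more peaks, 3771 by gene body overlap and 3284 by protein-coding bodies. The 3' UTR share was 39.5% and 40.0% under the same filters. By peak centre it was 62.9% of 1329 centres in coding transcripts, where stop and start codons are not separate classes. The intron share was 80.8% under either filter and 76.0% by peak centre. Lists outside the random range, 4 in the report, numbered 1 at a q-value of 1e-05 or less, 2 at a fold enrichment of 4 or more, 1 at or above the median, 2 with 2 or more peaks per gene, and 11 with all peaks over gene bodies. With 2 or more peaks per gene, the observed over expected ratio was 0 for the m6A, TGF-beta and ribosomal lists. Random lists averaged only 0.33, 0.38 and 0.23 members there, so 0 was within the range (percentiles 36.0, 33.9 and 39.6). The ribosomal ratio was also 0 under both fold filters, where random lists averaged 0.85 and 0.71, and was within the range. The ratio of MAPK kinases turned from below 1 to 1.97 over gene bodies (10 of 24 genes, percentile 99.3). Benjamini-Hochberg at 0.05 over all listed terms left 4 KEGG pathways and 382 GO terms, against 381 by the deposited FDR, which ranks without the 5 cellular component terms of p-value 0. Apart from filters that remove peaks and peak centres that merge element classes, both by construction, the cause was not tested. No list kept 5 members under a stricter peak threshold, so median folds have no value there. Depth limits folds at low background, where 8 fragments can make a peak.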

Other observations

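Taking all peaks over gene bodies, introns included, brought 11 of the 26 lists outside the random range, an assignment chosen after seeing the data. The m6A writers, erasers and readers had 14 of 24 members (mean of random lists 4.48, percentile 100), including Fto, Wtap, Virma, Mettl14 and Ythdc1. Chromatin regulators had 16 of 28 (mean 8.44, percentile 99.9), deadenylation and decay factors 12 of 28 (mean 5.22, percentile 99.9), insulin and mTOR signalling 11 of 24 (mean 6.47, percentile 97.9), and the dystrophin complex 10 of 20 (mean 5.55, percentile 98.4). Sarcomere genes stayed within the range with 5 of 38. Neuron markers fell below it with 2 of 24, Lrp1b and Syn1, as did endothelial and adipocyte markers with 0 of 18 (percentile 0.570). Brinp3 held 159 peaks, of which 153 were in introns, in a gene of 407713 bp. Thsd7a held 45, Angpt1 37, Tcf12 33 and Nfat5 32, all named after their values were seen. The strongest peak of the list, at 20.7 (16.0 to 26.3), lay in an intron of Bcas3 on chromosome 11 from 85673641 to 85674122.

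In the patterns below, the tests on genomic DNA in the libraries, weak intron peaks, low input background, dilution by intron peaks and the strand of both repeats were chosen after related values had been seen. The B1 12-mer was first found by scanning these peaks, so a second pair was run and the lower ratio is the one used.

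Most peaks lay in introns, outside the authors' gene table. Genomic DNA spread over the genome is argued against by the 97.1% of peak centres in gene bodies, and DNA recovered evenly over genes by neuron markers, at 0.260 times the length-matched expectation. Introns still held 65.4% of the 25% of peaks with smallest q-value, against weak peaks as the whole cause. They held 62.9% of peaks at or above the median input background, but 82.2% where background was under 2 and 14.0% where it was 32 or more. Low background may therefore account for part of the pattern. Median folds were close to those of exon peaks at like background (6.10 and 6.10 under 2). The caller's threshold sets the lowest fold at each background, so those medians decide nothing here. Reading the intron peaks as unspliced RNA remains a hypothesis, and without the IgG library RNA that binds beads or antibody alike stays open.

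Peaks held fewer DRACH motifs than the windows beside them. Against dinucleotide-shuffled peak sequence the ratio was 0.963, nearer to 1 than 0.919 but with an interval below it. The windows were not compared with their own shuffles. How much of the pattern base composition accounts for therefore cannot be told. In peaks with no soft-masked base the ratio was 0.948, against repeats as the whole cause. In the peaks of the authors' table it was 0.940, so DRACH was less dense there too, although the windows can lie in introns or outside the gene. GGACH against adjacent windows stood at 1.16 in those peaks and 1.10 in intron peaks, with overlapping intervals. By element, the DRACH ratio was above 1 only over stop codons, at 1.04 with an interval that includes 1. Shuffled sequence was not compared for the authors' peaks alone, so a signal in exons hidden by intron peaks stays open. Whether the pulldown enriched m6A sites could not be judged from the motif alone, and no biological explanation was tested.

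Intron peaks held UG repeats and antisense B1 sequence, a short interspersed element, on the strand of the gene. UG repeats of 6 units were in 6.56% (5.99 to 7.17) of intron peaks and 1.93% of windows 5 widths away, while CA repeats, their complement, were in 0.868% and 1.47%. The enrichments differed by a ratio of 5.78 (4.21 to 8.31) for UG over CA and 2.10 (1.45 to 3.01) for antisense over sense B1 12-mers, which reads mapped to either strand would not give for these pairs. The UG share was 8.37% in the 25% of peaks with smallest q-value against 6.03% in the other intron peaks, so weak peaks do not account for it. Proteins that bind UG-rich RNA may have been recovered with the antibody, a hypothesis that was not tested; sense B1 was also enriched, 2.86 times (2.15 to 3.95), and U and A runs of 12 were enriched nearly alike, 2.15 (1.88 to 2.43) and 1.92 times (1.58 to 2.30), so mapping of repeats stays open as a part.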
